A study of Mus musculus with 18 samples.

How the data were processed

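Neuro2A, a mouse neuroblastoma cell line, was transfected by nucleofection with a fusion of green fluorescent protein and the TATA-binding protein (TBP) that carried either 16 or 59 glutamines (16Q-TBP and 59Q-TBP). Per the labels, total RNA was extracted with Trizol at 24, 36 and 60 h after transfection, with 3 biological replicates per construct and time, and each of the 18 samples was hybridised to its own Agilent mouse miRNA array in 1 colour (Cy3). The labels call the replicates biological and do not say whether they came from separate cultures or days, so p-values measure the spread between these samples.

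The deposited scanner files hold spot intensity values made with Agilent Feature Extraction 9.5.1.1, per the file headers: a mean signal, a local background and a processed signal that was background-subtracted and detrended within the array, with a surrogate value for spots not above background. No scaling between arrays is recorded there. The deposited series table holds log2 values. Set against each array's scanner values, it equals log2 of the net intensity (mean signal minus the scanner offset) of the same spot, without scaling between arrays or centring, and its medians lay between 4.98 and 5.90 per array. It was used only as an alternative. The array carries 12553 spots, of which 11520 are probes for 566 mouse and 10 viral entries (1890 mouse and 40 viral probes, each in 5 to 20 spots and 1 to 4 probes per entry). miRNA names are those of the array design and can be old.

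The processed signal was averaged over the unflagged spots of each probe and divided by the array's 75th percentile over the 290 mouse probes well above background on all 18 arrays. On average 27.1% of mouse probes were well above background on an array, counting a probe as such where at least 50% of its unflagged spots carried the scanner software's flag. Scaled values were then floored at 0.0581, the median over arrays of the lowest scaled value among probes well above background, and taken to log2. A miRNA is the mean of its probes that were well above background on all 3 arrays of at least 1 group. This left 557 probes of 226 miRNA entries, 46 of them with a single probe, and 5 entries name several miRNAs. No spot was saturated. Control spots and viral probes were left out of the tests. For a miRNA not well above background on any array of a group, a fold is given as a bound against the lowest signal among probes well above background on those arrays.

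Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with 1 fit of 6 group means over the 18 arrays, 12 residual degrees of freedom and Benjamini-Hochberg adjustment over the 226 miRNAs at 0.05. The comparisons were 59Q versus 16Q at each time and averaged over the times, the dependence of that difference on time (moderated F test), and 36 h and 60 h versus 24 h within each construct. Errors are limma's standard error (SE) or the standard deviation (SD). 14 miRNA lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison. The miR-29 list among them was chosen from knowledge of the study on these same samples. Its tests, and those of the REST-linked list that holds it, are therefore not independent evidence. Lists with fewer than 3 tested members were only counted. Single values were also tested by exact permutation of the construct labels within times. miRNAs were named by a rule fixed beforehand: for 59Q versus 16Q the 10 largest rises and falls past the threshold, or the 5 smallest p where fewer than 5 passed, for time the 5 largest rises and falls past the threshold, all miR-29 members, the 3 smallest p for the dependence on time, and of each list described the 2 members with the largest moderated t.

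Arrays were checked for duplicates, and the highest correlation between any pair of arrays of different groups was 0.989 and within a group 0.985. The arrays lay on 3 slides, and each slide was scanned once, so a scan date adds nothing to the slide. The first slide held all 24 h arrays and 16Q replicates 1 and 2 at 36 h. The second held 16Q replicate 3 and all 59Q arrays at 36 h, all 16Q arrays and 59Q replicate 1 at 60 h. The third held 59Q replicates 2 and 3 at 60 h. Alternatives were normexp background correction (offset 50) on mean and background signals, quantile normalization, the percentile over all probes, no scaling, the brightest probe of a miRNA, the deposited log2 table, other filters, a floor 4 times higher, trend and robust options of eBayes, only the arrays compared, the replicate number or the slide as a block, and each array left out. Neighbouring genes were taken from the RefSeq annotation of GRCm38.p6 within 15 kb of Mir322, for names only, since the files use another build.

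The steps were tested on simulated data: 100 sets with the residual covariance of the real arrays, 226 miRNAs and 10 miRNAs changed at each size. For 59Q versus 16Q at 24 h, 40.7%, 85.5% and 98.2% of changes of 1, 2 and 3 on the log2 scale were called. For the average over times these shares were 78.7%, 99.1% and 100%. For the change of the difference from 24 h to 60 h they were 18.8%, 61.3% and 86.5%. With no change simulated, 2 of 100 sets gave any call at 24 h, with up to 98 calls in a single set, so false calls came in blocks.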

Results

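miRNA levels were measured in Neuro2A mouse neuroblastoma cells that expressed TBP with a normal-length (16Q) or an expanded (59Q) polyglutamine tract. TBP is a general transcription factor, and expansion of its polyglutamine tract causes spinocerebellar ataxia type 17. Each construct was sampled at 24, 36 and 60 h after transfection with 3 biological replicates, which gave 6 groups and 18 arrays. Between 19.7% and 37.3% of the probe spots of an array were well above background, and the number of arrays limits the precision. 226 of 566 mouse miRNA entries could be tested. All 8 entries of the miR-200 family and the miR-183 cluster, miRNAs of epithelial and sensory cells, were too dim for the tests.

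Arrays of the same group were at times less alike than arrays of different groups, whose correlations ranged from 0.544 to 0.989. The first 2 principal components held 47.4% and 31.8% of the variance. Replicates 1 and 2 of 16Q at 24 h, replicate 2 of 59Q at 36 h and replicate 1 of 59Q at 60 h stood apart. Their median correlations with the other 17 arrays were 0.801, 0.773, 0.759 and 0.762, against 0.834 to 0.929 elsewhere. The 2 arrays of 16Q at 24 h lay close to each other on the first component (-12.6 and -12.3), and replicate 3 lay at 0.40. Within that group replicate 3 was therefore the one that differed, with correlations between replicates from 0.804 to 0.984. Settings without both arrays drop 2 replicates that resemble each other. Correlations between replicates ranged from 0.653 to 0.900 in 59Q at 60 h and from 0.959 to 0.983 in 16Q at 60 h.

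**Figure D1:**
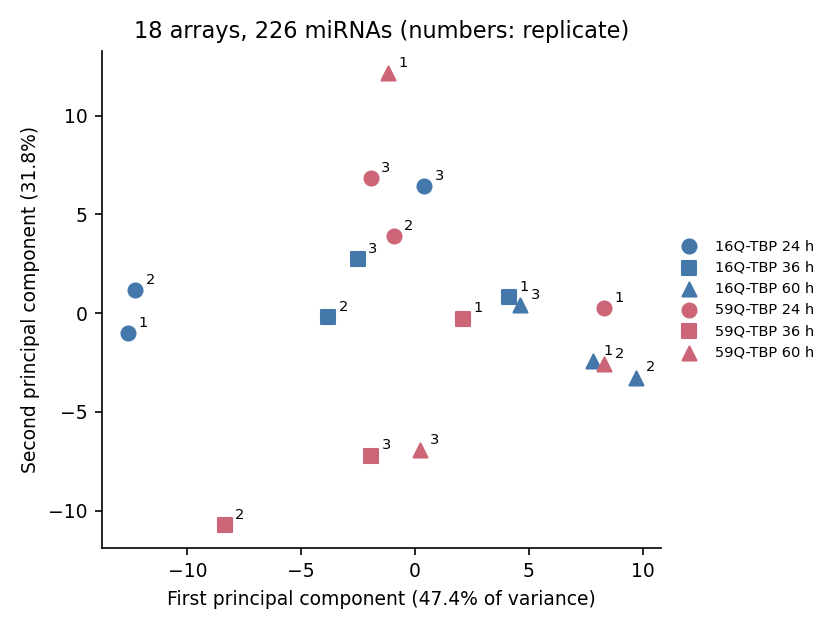
Principal components of log2 scaled values of 226 miRNAs on 18 arrays, with the first component (47.4% of variance) on the x axis and the second (31.8%) on the y axis. Each point is 1 array, coloured by construct, shaped by time and numbered by replicate, and replicates of most groups lie apart.

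The first comparison asked which miRNAs differ between cells with expanded and normal-length TBP. miR-322, the mouse member of the miR-15/16 seed family encoded on the X chromosome, was higher in 59Q than in 16Q at every time. Its log2 scaled signal at 24 h was 1.02 ± 0.23 (SD, n = 3) in 59Q and -2.00 ± 0.41 in 16Q. The rise was 8.10-fold at 24 h (log2 3.02, SE 0.29, limma adjusted p = 2.61e-06), 6.79-fold at 36 h (log2 2.76, SE 0.29, limma adjusted p = 9.08e-06) and 3.04-fold at 60 h (log2 1.60, SE 0.29, limma adjusted p = 0.00872). Averaged over the times it was 5.51-fold (log2 2.46, SE 0.17, limma adjusted p = 1.58e-08). Each of the 9 arrays of 59Q lay above every 16Q array of its time, and an exact two-sided permutation within times gave p = 0.00025, the smallest that 8000 relabellings allow. That p is for miR-322 alone, the top of 226 miRNAs in the same values, and is not adjusted for this choice. At a single time the exact p was 0.1, the smallest possible for 3 against 3.

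miR-322 was the only miRNA past the threshold at each time and in the average, while 46, 35, 1 and 2 miRNAs had an unadjusted p under 0.05 at 24 h, 36 h, 60 h and averaged. Its signal came from 1 of its 2 probes, which was well above background on all 18 arrays. The other probe lay at the floor on 15 arrays, was well above background on 4, and differed by 0.11, 0 and 0.84 on the log2 scale at 24, 36 and 60 h, the last from 59Q replicate 1 alone. Without a filter on dim probes, which averages both probes, the log2 differences were 1.56 at 24 h (adjusted p = 0.0687), 1.38 at 36 h (adjusted p = 0.0999) and 1.22 at 60 h (adjusted p = 0.537), and none of these passed. At 60 h the call was also lost with normexp background (log2 0.81, adjusted p = 0.835), the deposited log2 table (log2 1.37, adjusted p = 0.164), only the arrays compared (adjusted p = 0.0912) and without 16Q replicate 1, 16Q replicate 2 or 59Q replicate 2 (log2 1.53, 1.61 and 1.55). Over the alternatives the adjusted p of miR-322 ranged from 1.2e-06 to 0.0687 at 24 h, 1.62e-06 to 0.0999 at 36 h and 0.000955 to 0.835 at 60 h, and its log2 difference at 24 h was 1.97 with normexp and 1.93 in the deposited table. Within 1 slide, the log2 difference was 3.02 at 24 h (all arrays), 2.69 at 36 h (1 array of 16Q and 3 of 59Q) and 1.46 at 60 h (3 arrays of 16Q and 1 of 59Q), and with slide as a block the average was 2.39.

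**Figure D2:**
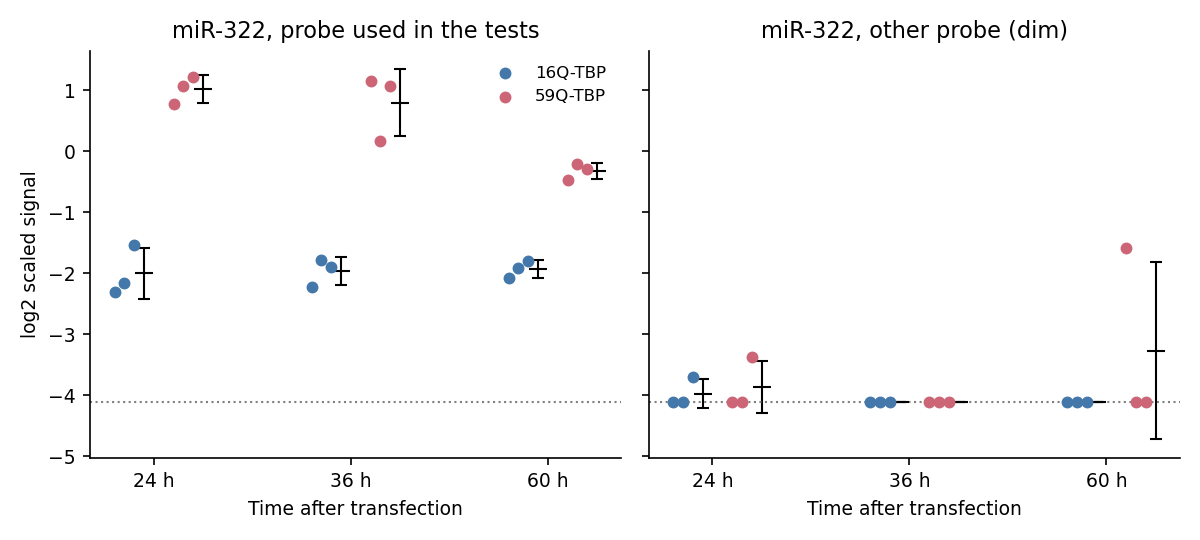
Log2 scaled signal of the pair of miR-322 probes (y axis) by time after transfection (x axis). Points are arrays, black bars the mean and SD of 3 arrays, and the dotted line the floor. In the probe used for the tests the 59Q arrays lie above all 16Q arrays at each time, and the other probe is at the floor on 15 of 18 arrays.

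At 24 h the next smallest p values belonged to miR-450a-3p, a neighbour of miR-322 (log2 difference 1.27, SE 0.41), miR-689 (1.85, SE 0.60), miR-710 (1.58, SE 0.56) and miR-485* (-1.97, SE 0.68, with 2 of 3 arrays of 59Q above background), each with limma adjusted p = 0.192. Without 16Q replicate 3 the count at 24 h was 50 in place of 1. At 36 h let-7i (log2 difference -1.33, SE 0.37), miR-30e (-1.11, SE 0.32), miR-29b (-1.22, SE 0.38) and miR-881 (-1.04, SE 0.33) followed miR-322, each with limma adjusted p = 0.201. At 60 h they were miR-669a (0.71), miR-7a, miR-696 (-0.81) and miR-423-5p (-0.72), each with limma adjusted p = 0.947. miR-7a was not well above background on any 16Q array and was above it on 1 of 3 arrays of 59Q. Its bound of 1.42-fold rests on that array, and the 95% interval of its log2 difference ran from -0.17 to 2.67. Averaged over the times they were miR-681 (0.46), miR-149 (-0.35), miR-30e (-0.33) and miR-689 (0.57), each with limma adjusted p = 0.999. With slide as a block 49 miRNAs passed at 60 h, where that fit sets 59Q replicate 1 alone against 3 arrays of 16Q.

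The miR-29 family, which targets extracellular matrix genes and the BACE1 transcript and was chosen by the study on these samples, was examined in each comparison. At 36 h miR-29a, miR-29b and miR-29c had log2 differences of -1.16 (SE 0.40), -1.22 (SE 0.38) and -1.10 (SE 0.37), with limma adjusted p of 0.217, 0.201 and 0.213. All 3 arrays of 59Q lay below every 16Q array for each member, and the exact permutation p of the family mean was 0.1, the smallest possible. Adjusted over the list alone, 3 of 3 passed at 36 h, which is not independent evidence of the direction. Camera gave adjusted p = 0.0131 for the family at 36 h, and adjusted p = 0.493 with an estimated correlation, and this test has the same limit, since the list came from the study on these samples. Within the second slide the 3 differences were -1.20, -1.36 and -1.19, with 1 array of 16Q, and within that slide at 60 h they were 0.94, 0.90 and 0.72, with 1 array of 59Q. At 24 h they were 0.48, 0.48 and 0.40, and turned below 0 with no scaling and in the deposited log2 table, and at 60 h they were 0.08, 0.02 and -0.0032, where the probes of miR-29b and of miR-29c disagreed in sign. Averaged over the times they were -0.20, -0.24 and -0.23, and exact permutation of the family mean gave p = 0.427. The averaged family median turned to 0.0136 in the deposited log2 table and 0.00697 with slide as a block.

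**Figure D3:**
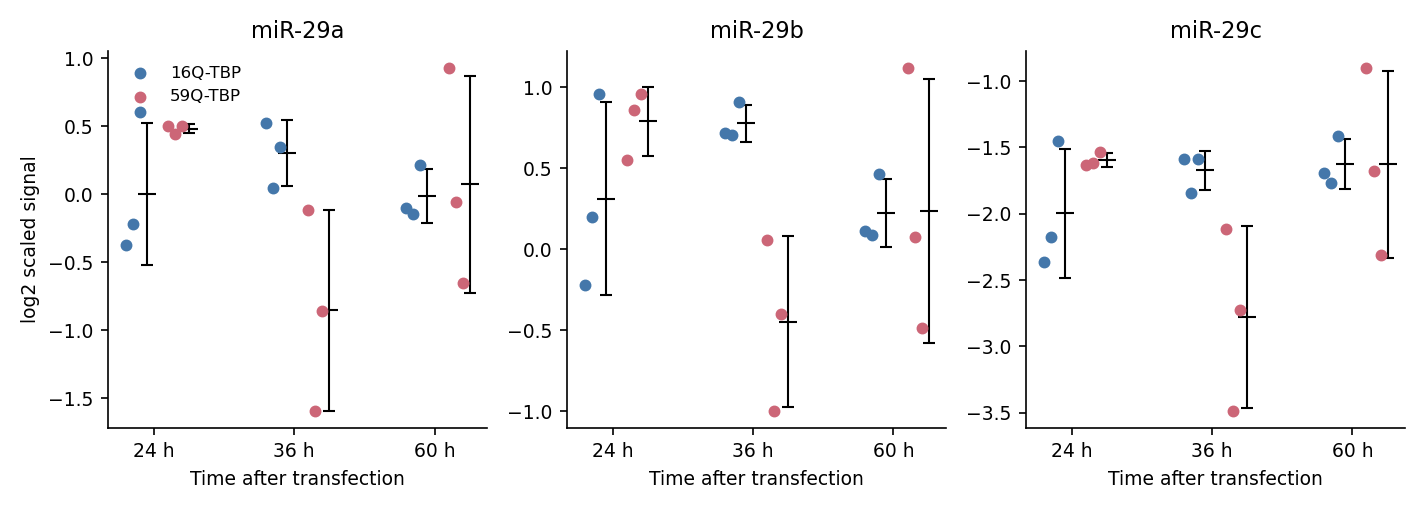
Log2 scaled signal of miR-29a, miR-29b and miR-29c (y axes, each with its own range) by time after transfection (x axis). Points are arrays and black bars the mean and SD of 3 arrays. At 36 h the 59Q arrays lie below the 16Q arrays for each member, with a family mean of -1.36 ± 0.65 against -0.20 ± 0.14 (n = 3).

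Among the other fixed lists at 36 h, no member passed over all miRNAs. All 11 tested members of the miR-17 to miR-92 and paralogous clusters, proliferation-linked miRNAs, were lower in 59Q (median log2 difference -0.87, camera adjusted p = 0.0081, adjusted p = 0.493 with an estimated correlation), with miR-106b at -1.08 and miR-93 at -0.96. Of the REST-linked and Huntington-linked miRNAs, 5 of 13 were tested and 3 of them are the miR-29 members, so this list is not independent of that family (median -1.10, camera adjusted p = 0.032, adjusted p = 0.493 with an estimated correlation). The stress and inflammation miRNAs had a median of -0.49 (10 tested, camera adjusted p = 0.0403, adjusted p = 0.493 with an estimated correlation), with miR-146a at -0.85 and miR-125b-5p at -1.01. The Dlk1-Dio3 imprinted cluster (median 0.13, 11 tested, adjusted p = 0.0403, adjusted p = 0.493 with an estimated correlation) and star strands (median 0.31, 24 tested, adjusted p = 0.0131, adjusted p = 0.448 with an estimated correlation) were shifted up by camera relative to the other miRNAs, and the median of all miRNAs was -0.19. The medians of the miR-29, miR-17 to miR-92 and REST-linked lists stayed below 0 under every scaling tried, but were -0.38, -0.15 and -0.33 with no scaling and -0.27, -0.01 and -0.12 in the deposited table, while the stress list turned to 0.18 with no scaling and 0.15 in the deposited table, and the Dlk1-Dio3 and star strand lists turned to -0.14 and -0.26 with normexp. Without the 4 arrays least correlated with the others, the medians were -0.79 for miR-29, -0.57 for miR-17 to miR-92, -0.75 for the REST-linked list, -0.27 for the stress list, 0.35 for Dlk1-Dio3 and 0.04 for star strands, and with the 2 array scores as covariates -0.52, -0.30, -0.51, -0.22, 0.09 and -0.14. The counts adjusted over the list alone were 0 for the miR-17 to miR-92, stress, Dlk1-Dio3 and star strand lists and 3 for the REST-linked list. The 23 small-RNA control probes had a median difference of -0.62 at 36 h (0.16 with no scaling) and 0.81 at 24 h (0.10 with no scaling), where 0 passed in limma at either time and 1 and 4 had an unadjusted p under 0.05. Under the main scaling 0 of them were higher in 59Q at 36 h and 23 at 24 h, and with no scaling 15 were higher at each time.

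The lists that shifted at 24 h and 60 h were those of the Sfmbt2 intron and of entries open to RNA quality. The Sfmbt2 cluster, a large repeat-derived miRNA cluster (the miR-297, miR-466, miR-467 and miR-669 families), had a median log2 difference of -0.81 at 24 h (20 tested, camera adjusted p = 1.9e-10, adjusted p = 0.117 with an estimated correlation) and 0.45 at 60 h (adjusted p = 1.63e-05, adjusted p = 0.65 with an estimated correlation). miR-466h was at -1.33 and miR-467a*/miR-467d* at -1.50 at 24 h, and miR-669a at 0.71 and miR-669b at 0.50 at 60 h. At 24 h 17 members were lower in 59Q and 3 higher, among them miR-467a (-1.02 in 16Q, -0.37 in 59Q), against its star strand. Entries outside the list were lower as well, such as miR-877* (-0.10 in 16Q, -1.54 in 59Q) and miR-672 (-1.58, -3.05), beside a median difference of 0.25 over all miRNAs. The shift was thus neither shared by all members nor particular to the cluster. The list of entries open to RNA quality holds 15 entries grouped beforehand as GC-rich or as fragments of other RNAs, without a check of their sequences. Its medians were 0.69 at 24 h (camera adjusted p = 0.0162, adjusted p = 0.899 with an estimated correlation) and -0.51 at 60 h (camera adjusted p = 8.46e-05, adjusted p = 0.92 with an estimated correlation). In it miR-689 was at 1.85 and miR-721 at 1.14 at 24 h. Without both 16Q arrays that stand apart at 24 h, which leaves 1 array of 16Q there, the medians at 24 h were -0.12 for the Sfmbt2 cluster and 0.19 for the entries open to RNA quality, and with the 2 array scores as covariates -0.08 and 0.10. Without 59Q replicate 1 at 60 h, in the setting that leaves out 4 arrays, the median of the entries open to RNA quality was -0.06 at 60 h and that of the Sfmbt2 cluster 0.52, and with the 2 array scores 0.0027 and 0.19. With slide as a block the medians at 60 h were -1.32 for the entries open to RNA quality and 0.52 for the Sfmbt2 cluster. At 60 h the Sfmbt2 median turned to -0.0071 with normexp, and that of the entries open to RNA quality to 0.05 with no scaling and 0.04 in the deposited table, while at 24 h both kept their sign under the scalings tried. No member of either list passed over all miRNAs or adjusted over the list alone. Neuronal miRNAs (12 tested), ataxin-1-regulating miRNAs (6), the let-7 family (8), p53-linked miRNAs (3) and markers of other cell types (6) had no camera call in these comparisons, with camera adjusted p from 0.0723 upward. Adjusted over the list alone, 3 ataxin-1-regulating miRNAs, 2 p53-linked miRNAs and 1 let-7 member passed at 36 h, and none over all miRNAs.

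Whether the difference between the constructs depends on time was tested directly. In limma no miRNA passed, and 50 had an unadjusted p under 0.05. The 3 smallest p were those of miR-322, let-7i and miR-467a*/miR-467d*, each with limma adjusted p = 0.215. The 59Q minus 16Q difference of miR-322 was lower by 1.42 on the log2 scale at 60 h than at 24 h, without passing. Without 16Q replicate 3 at 24 h 30 miRNAs passed, and with slide as a block 55 did.

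The last comparisons asked how miRNA levels change with time in each construct. miR-210, a hypoxia-induced miRNA, and miR-146a, an NF-kB-induced miRNA, rose from 24 h to 60 h in both constructs. miR-210 rose 3.93-fold in 16Q (log2 1.97, SE 0.25, limma adjusted p = 0.000151) and by 1.59 on the log2 scale in 59Q (SE 0.25, limma adjusted p = 0.00228). miR-146a rose 2.87-fold in 16Q (log2 1.52, SE 0.28, limma adjusted p = 0.00373) and 2.47-fold in 59Q (log2 1.31, SE 0.28, limma adjusted p = 0.0184). miR-214 rose 2.32-fold in 16Q (log2 1.22, SE 0.23, limma adjusted p = 0.00373), and its log2 change in 59Q was 0.82 (SE 0.23, limma adjusted p = 0.133). For these 3 miRNAs the 60 h arrays lay above every 24 h array of the construct. miR-322 fell by 1.34 on the log2 scale in 59Q (SE 0.29, limma adjusted p = 0.0184). With normexp background none of these calls was kept, and the log2 changes were 0.68 and 0.42 for miR-210, 0.77 and 0.63 for miR-146a in 16Q and 59Q, 0.74 for miR-214 in 16Q and -1.08 for miR-322 in 59Q. With slide as a block none was kept either (adjusted p of 0.0678 or more). In that fit the log2 changes were 2.01 and 1.81 for miR-210, 1.51 and 1.70 for miR-146a in 16Q and 59Q, 1.30 for miR-214 in 16Q and -1.60 for miR-322 in 59Q. It ties the first slide to the second only through 16Q at 36 h, with replicates 1 and 2 against replicate 3, so these values rest on few arrays. In 16Q the log2 changes of miR-146a and miR-214 were 0.60 and 0.29 with no scaling and 0.58 and 0.33 in the deposited table, without passing, and with a floor 4 times higher that of miR-210 was 0.33 in 16Q and 0.30 in 59Q. Without both 16Q arrays that stand apart at 24 h, which leaves 1 array of 16Q there, the log2 changes of miR-210, miR-146a and miR-214 in 16Q were 1.76, 1.09 and 0.90, without passing (adjusted p = 0.0525, 0.43 and 0.43). In 59Q the rise of miR-146a also did not pass with no scaling (adjusted p = 0.1), the brightest probe (adjusted p = 0.0648), or without 24 h replicate 1, 2 or 3 or 60 h replicate 2 (adjusted p from 0.0606 to 0.0978). With only the arrays compared, miR-210, miR-146a and miR-322 did not pass in 59Q (adjusted p = 0.345, 0.44 and 0.361). The fall of miR-322 also did not pass without 24 h replicate 2 or 3 or 60 h replicate 2 or 3 (adjusted p from 0.0547 to 0.136), nor with no scaling, the deposited table or no filter (log2 -0.996, -0.82 and -0.37).

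**Figure D4:**
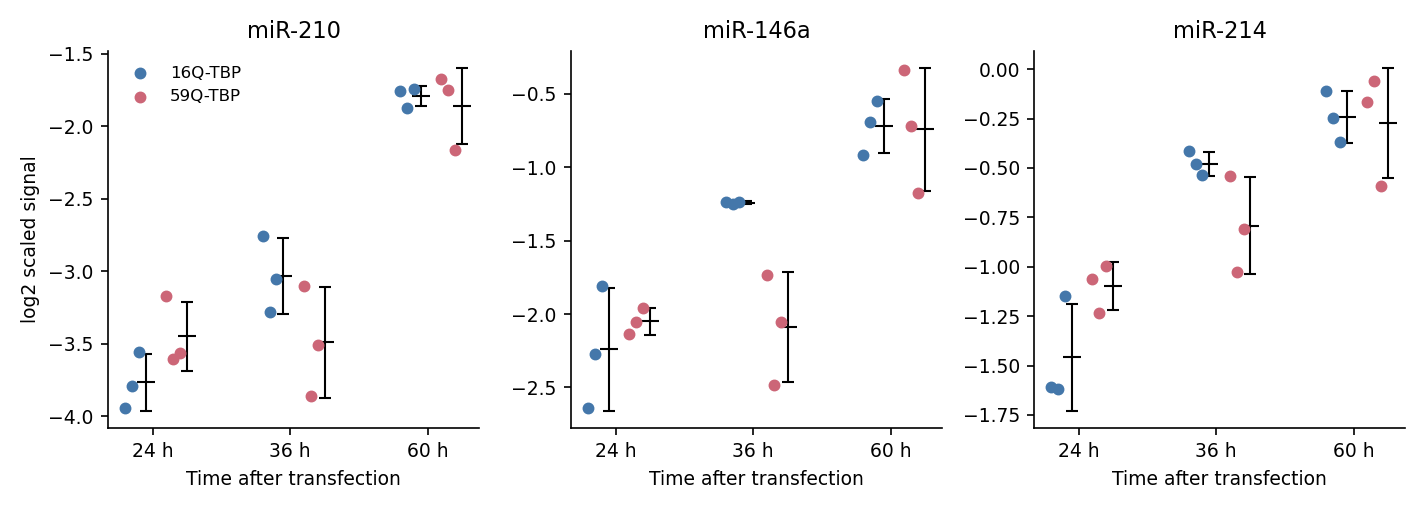
Log2 scaled signal of miR-210, miR-146a and miR-214 (y axes, each with its own range) by time after transfection (x axis). Points are arrays and black bars the mean and SD of 3 arrays. In both constructs the 60 h arrays lie above the 24 h arrays, with miR-210 at -1.79 ± 0.07 against -3.76 ± 0.20 in 16Q (n = 3).

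In 16Q, 80 miRNAs differed between 60 h and 24 h, 57 higher and 23 lower. The largest rises were those of miR-689 (9.63-fold), miR-680 (6.43-fold), miR-671-5p (5.34-fold), miR-150* (5.32-fold) and miR-188-5p (5.22-fold), with limma adjusted p from 0.00373 to 0.015. The largest falls were those of miR-207 (4.52-fold), miR-485* (4.50-fold), miR-297b-3p/miR-297c*/miR-297a* (4.42-fold), miR-467a*/miR-467d* (3.98-fold) and miR-672 (3.89-fold), with limma adjusted p from 0.0183 to 0.0248. miR-485* and miR-672 were well above background on 1 of 3 arrays of 16Q at 60 h. Of the entries open to RNA quality 10 of 15 rose (13 adjusted over the list alone, median 1.26, camera adjusted p = 0.00103), and of the Sfmbt2 cluster 12 of 20 fell (18 adjusted over the list alone, median -1.10, adjusted p = 4.23e-08), among them miR-669b (-1.18) and miR-669a (-1.45). With an estimated correlation camera gave adjusted p of 0.925 and 0.253. In the Sfmbt2 cluster 18 members lay lower at 60 h and 2 higher, among them miR-467a (-1.02 at 24 h, -0.32 at 60 h). In the Dlk1-Dio3 cluster 4 of 11 rose, among them miR-134 (log2 2.18) and miR-370 (1.57), in the stress list 4 of 10 rose, and of the markers of other cell types 3 of 6 rose, among them miR-214 and miR-199a-5p (1.15). Adjusted over the list alone these counts were 4, 4 and 5. Of 24 star strands 7 rose and 6 fell (15 adjusted over the list alone), among them miR-150* (2.41) and miR-199b* (1.14). Camera gave adjusted p = 0.871 for each of the Dlk1-Dio3, stress, other cell type and star strand lists, so none was called as a list. Among all 226 miRNAs 57 rose and 23 fell.

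The 16Q count varied with single arrays and with scaling. It was 13, 6, 19 and 7 without 24 h replicate 1, 24 h replicate 2, 60 h replicate 1 and 60 h replicate 2. Without both 16Q arrays that stand apart at 24 h, a setting chosen after the data were seen, it was 0, and the median change of the 80 in their called direction was 0.81 in place of 1.46. That setting leaves 1 array of 16Q at 24 h, with the spread taken from the other groups, so part of the fall in the count follows from the single array. It was 41 without scaling (7 higher and 34 lower), 5 in the deposited log2 table, 3 with normexp background and 0 with slide as a block. The small-RNA control probes had a median log2 change of 0.73 between the same groups (0 passed in limma and 3 had an unadjusted p under 0.05), and -0.20 with no scaling. All 23 of them rose under the main scaling and 1 rose with no scaling. The medians of the entries open to RNA quality and of the Sfmbt2 cluster kept their sign under the scalings tried, but were 0.82 and -0.53 without both 16Q arrays that stand apart at 24 h and -0.02 and -0.28 with the 2 array scores as covariates.

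In 59Q, 3 miRNAs differed between 60 h and 24 h, and 11 had an unadjusted p under 0.05. The markers of other cell types (median 0.44, 6 tested, camera adjusted p = 0.0428, adjusted p = 0.205 with an estimated correlation) lay higher, with miR-214 passing adjusted over the list alone, and the miR-17 to miR-92 clusters lower (median -0.43, 11 tested, camera adjusted p = 0.0428, adjusted p = 0.944 with an estimated correlation). These medians turned to -0.05 with normexp and to 0.10 in the deposited table. The entries open to RNA quality had a median of -0.06 and the Sfmbt2 cluster 0.06 there. Without 59Q replicate 1 at 60 h, the count was 18 in place of 3. With the 2 array scores as covariates 26 miRNAs were called higher and 17 lower, although p-values in that fit are too small. At 36 h versus 24 h no miRNA passed in limma in either construct, with 26 in 16Q and 64 in 59Q at an unadjusted p under 0.05, and without 59Q replicate 1 at 36 h 63 miRNAs passed in 59Q. Without 16Q replicate 3 at 24 h, 8 passed in 16Q.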

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

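The tests of the 2 array scores, of single arrays, of the miR-322 cluster, of CAG-repeat RNA and of the difference in time effect were chosen or revised after the results were seen, and so was the test of the lists for a change of the construct difference with time. The bounds for RNA quality and for bright miRNAs were set before the list medians, but after single members (miR-689 and miR-680, let-7i and miR-106b) had been seen.

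4 list results were singled out by camera for the change of the difference between the constructs with time, and their calls were lost with an estimated correlation. The Sfmbt2 cluster had a median change of 1.01 on the log2 scale from 24 h to 36 h (adjusted p = 5.11e-07, adjusted p = 0.185 with an estimated correlation) and 1.19 from 24 h to 60 h (adjusted p = 9.17e-11, adjusted p = 0.106 with an estimated correlation). The entries open to RNA quality had -1.30 from 24 h to 60 h (adjusted p = 0.000427, adjusted p = 0.978 with an estimated correlation). Star strands had a median change of 0.00092 and a mean of 0.37 from 24 h to 36 h (adjusted p = 0.00568, adjusted p = 0.185 with an estimated correlation). Without both 16Q arrays that stand apart at 24 h, which leaves 1 array of 16Q there, the Sfmbt2 medians were 0.25 and 0.53, that of the entries open to RNA quality -0.76, and star strands had a median of 0.02 and a mean of 0.11. Without the 4 arrays least correlated with the others the Sfmbt2 medians were -0.02 and 0.53 and that of the entries open to RNA quality -0.30, and with the 2 array scores as covariates they were -0.17, 0.21 and -0.20. Outside the tests, the murine gammaherpesvirus entry mghv-miR-M1-2 had a probe well above background on 18 of 18 arrays, and 23 small-RNA control probes (4.5S, MRP, U1, U4, U6, U32 and vault RNA) were well above background on all 18 arrays.

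miR-322 was higher in 59Q at all 3 times. Scaling or background correction as the whole cause is argued against by an averaged log2 difference of 1.52 or more under normexp, quantile, all-probe percentile and no scaling, the variation between replicate arrays by 2.46 with the array scores on the 2 leading residual axes as covariates, and slide by 2.39 with slide as a block. A rise of the whole Mir322 cluster is argued against by a median of 0.22 over 3 tested neighbours (miR-503, miR-542-3p and miR-450a-3p, with upper 95% limits of 0.37, 0.74 and 0.79). However, miR-450a-3p was at 1.27 at 24 h, a value that went down to 0.04 over the alternatives. Also, 7 of the 10 other entries of the cluster were not tested, 5 of them well above background on no array, among them miR-322* and miR-351. CAG-repeat RNA of the transfected construct could bind the miR-322 probe, since mature miR-322 opens with CAG triplets. Its difference fell by 1.42 from 24 h to 60 h (log2, limma unadjusted p = 0.003). The 2 miR-322 probes differed by 2.91 on the log2 scale in their response at 24 h, which this cause would also give, though the dim probe lay at the floor on 15 arrays. By contrast, miR-15a, miR-15b, miR-16, miR-195 and miR-497, which share AGCAGC, had averaged differences from -0.22 to 0.17. At 24 h theirs were from 0.05 to 0.60 without passing, beside a median of 0.25 over all miRNAs. Probe binding and a rise of mature miR-322 with polyglutamine length therefore cannot be told apart here, since probe sequences were not used.

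More miRNAs were called at 60 h versus 24 h in 16Q (80) than in 59Q (3) in the main fit. This order turned with the 2 array scores as covariates, with 9 higher and 10 lower in 16Q against 26 higher and 17 lower in 59Q. RNA quality or labelling is a candidate cause: the entries open to it had a median change of 1.26 in 16Q against -0.06 in 59Q. With the 2 array scores as covariates it was -0.02 in 16Q, but these scores can also remove a real change. Slide cannot be told apart from time in either construct, since no 24 h array shared a slide with a 60 h array. With replicate 3 as the only 16Q array at 24 h, the median change of the 80 miRNAs in their called direction was 0.81 in place of 1.46, so how much single arrays account for stays open. A time effect that differs between the constructs stays open as well: 0 miRNAs passed the direct test. A bound set beforehand took that count as evidence against it and was replaced, and its replacement replaced again, after the result was seen, and a simulation run last shows why it was too weak, since the direct test called 18.8% of differences of 1 and 61.3% of differences of 2 on the log2 scale.

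The miR-29 family was lower in 59Q at 36 h without passing over all miRNAs. With the 2 array scores as covariates the median difference was -0.52 in place of -1.16, and without the 4 arrays least correlated with the others it was -0.79. The scores were computed from all values, group differences included, so they can also remove a construct effect. How much the variation between replicate arrays accounts for therefore stays open. The part of the scaling stays open too, since the median was -0.38 with no scaling and -0.27 in the deposited table. Of the 23 small-RNA control probes 0 were higher in 59Q at 36 h under the main scaling, and 15 with no scaling. Slide cannot be told apart: the value of -1.20 with slide as a block met the bound set beforehand, but rests on a single 16Q array, and the same fit gave 0.90 at 60 h. A shift of bright miRNAs in general was not decided either. The miR-17 to miR-92 list had a median of -0.87 and the let-7 family -0.30. These lists hold dim members, such as miR-17 (-2.43 in 16Q at 36 h), so they do not measure brightness. Bright entries differed at 36 h. miR-709, an entry open to RNA quality, hardly moved (3.68 in 16Q, 3.67 in 59Q), and miR-202-3p moved little (1.46, 1.38). miR-130a (1.36 in 16Q, 0.63 in 59Q), miR-24 (1.44, 1.05) and miR-22 (1.32, 0.95) were lower in 59Q. The 131 miRNAs with probes well above background on all 18 arrays had a median difference of -0.34, against -0.19 over all 226. An effect of the expanded tract on the family stays open.

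Other splits of the arrays were counted. For 3 arrays against 3 the 10 splits are too few for a share under 0.05. The real counts of 1 at 24 h, 36 h and 60 h for 59Q versus 16Q compare with 0 in the highest other split, and 1 of 10 splits gave as many each time. For 36 h versus 24 h the real count was 0 in both constructs, as in all 10 splits, and for 60 h versus 24 h in 16Q it was 80 against 0. For 60 h versus 24 h in 59Q the real count was 3, and 3 of 10 splits gave as many. There a split that put 24 h replicate 1 with 60 h replicates 2 and 3 gave 74, which points to a structure of the arrays other than time. For the average over times, 3 of 100 splits, the real one included, gave at least the real count of 1, a share under 0.05. A wrong split gave 76, so a count of 1 is a weak measure and chance is not excluded by it. For the dependence on time, the real count and the highest other were 0, and since 100 of 100 splits reach a count of 0 by construction, the splits say nothing there.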

How the results depend on the processing

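The 4-array, score and 24 h pair settings, the within-slide values and the list medians under other scalings were chosen after the results were seen. The averaged miR-322 difference passed under all 15 alternatives (log2 1.39 to 2.67, adjusted p from 5.45e-09 to 0.000984) and in all 18 fits with an array left out (2.40 to 2.57). Counts of 59Q versus 16Q moved from 1 at 24 h to 0 with no filter, at 36 h to 2 with a floor 4 times higher and with only the arrays compared, at 60 h to 0 with normexp, the deposited table, no filter and only the arrays compared and to 49 with slide as a block, in the average to 2 with slide as a block. At 36 h with no filter the 1 call was miR-297c in place of miR-322. The dependence on time moved from 0 to 1 with the higher floor and to 55 with slide as a block. At 36 h versus 24 h it moved from 0 to 1 in 16Q with no filter and the higher floor, and in 59Q to 1 and 2. At 60 h versus 24 h in 16Q it moved from 80 to 3 with normexp, 41 with no scaling, 5 in the deposited table, 27 with no filter, 26 with the higher floor and 0 with slide as a block, and in 59Q from 3 to 0 with normexp, 1 with no scaling, 1 with slide as a block and 0 with only the arrays compared. In the added settings, leaving out the 4 arrays least correlated with the others gave 4 (16Q, 60 h), 13 (59Q, 36 h) and 43 (59Q, 60 h), and the scores on the 2 residual axes gave 11 (36 h), 2 (average), 7 and 19 (16Q, 36 h and 60 h) and 2 and 43 (59Q). These scores came from the same data, so their p-values are too small. They were computed from all values, group differences included, so they can also remove a real difference between groups. Leaving out both 16Q arrays that stand apart at 24 h gave 0 of 80, with 1 array of 16Q left there, which lowers the count in itself. Slide blocks rest on few arrays, since 59Q at 60 h then leans on replicate 1. The cause of the other moves was not tested. With an array left out the counts ranged from 1 to 50 at 24 h, 1 to 1 at 36 h, 0 to 1 at 60 h, 1 to 1 averaged, 0 to 30 for the dependence on time, 0 to 8 and 6 to 99 in 16Q (36 h and 60 h) and 0 to 63 and 1 to 18 in 59Q. The list calls were 14 with camera, 0 with an estimated correlation and 4 with fry, which were the Sfmbt2 cluster and the entries open to RNA quality at 60 h in 16Q and the markers of other cell types at 60 h in 16Q (adjusted p = 0.00699) and in 59Q (adjusted p = 0.0203).

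Signs of single miRNAs turned only for values that did not pass. At 24 h miR-29a, miR-29b and miR-29c were at -0.23, -0.23 and -0.31 with no scaling, -0.19, -0.18 and -0.16 in the deposited table, and -0.12, -0.17 and -0.15 both without the 4 arrays and without the pair at 24 h, and miR-29a and miR-29c at -0.0355 and -0.0466 with the 2 scores. At 60 h miR-29a was at -0.0641 (percentile over all probes) and -0.34 (without the 4 arrays), miR-29b at -0.0165 (quantile, as the family median), -0.13 (percentile over all probes), -0.43 (without the 4 arrays) and -0.12 (2 scores), and miR-29c at 0.55 (no scaling), 0.0295 (brightest probe), 0.32 (deposited table), 0.0919 (higher floor) and 0.72 (slide). With an array left out at 60 h they ranged from -0.34 to 0.45, -0.43 to 0.38 and -0.37 to 0.34. In the average, miR-29a was at 0.0102 (no scaling), 0.0203 (deposited table) and 0.0732 (slide), miR-29b at 0.00697 (slide), miR-29c at 0.0136 (deposited table), miR-681 at -0.012 (normexp) and miR-689 at -0.00034 (without the pair at 24 h).

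With the replicate block the counts were 1, 1, 1 and 1 for 59Q versus 16Q, 0 for the dependence on time, 0 and 68 in 16Q and 0 and 3 in 59Q. Over the 4 list alternatives, the replicate block among them, the list calls ranged from 0 to 13. Deviations of same-numbered arrays of the constructs correlated between -0.51 and 0.67, and 2 of 9 correlated best with their own number, so the numbers were not taken as pairs. No scaling shifted the median of all miRNAs by -0.60, 0.66 and 0.46 at 24, 36 and 60 h for 59Q versus 16Q and by -0.86 for 60 h in 16Q, the deposited table by -0.39, 0.50, 0.19 and -0.29, and normexp by -0.17, -0.17 and -0.26 at the 3 times. The planned total gene signal was not run because the files hold no such column, and scan date because it equals the slide. Array weights did not converge and were not used, and residual factors as covariates were dropped because they are orthogonal to the groups and cannot move a difference, so the scores on their axes took their place. The share of spots above background limits the tests to 226 entries.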

Other observations

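Outside the lists that shifted, single members also passed in 16Q between 24 h and 60 h. Of 12 neuronal miRNAs 2 rose and 1 fell (1 adjusted over the list alone), with miR-134 at 2.18 on the log2 scale and miR-7a at least 2.16-fold lower at 60 h, where it was not well above background on any 16Q array. Of 11 members of the miR-17 to miR-92 and paralogous clusters 1 fell, miR-25 (-1.35), and of 5 REST-linked miRNAs 1 rose, miR-212 (0.89), with 0 adjusted over the list alone in both lists. In 59Q 2 of 10 stress miRNAs rose, miR-210 and miR-146a. 2 miRNAs were called between 24 h and 60 h in both constructs, and 51 of the 80 called in 16Q had the same sign in 59Q.

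In a search over 691 single probes, a wider set than the 557 of the main tests, a probe of miR-681 had an averaged log2 difference of 1.14 between 59Q and 16Q (limma adjusted p = 0.0232), besides that of miR-322. Over its 4 probes, the miR-681 entry was at 0.46 (limma adjusted p = 0.999), and at -0.012 with normexp. Of the other murine gammaherpesvirus entries, mghv-miR-M1-8 had a probe well above background on 5 arrays and mghv-miR-M1-6 on 4.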
